A study of Mus musculus with 4 samples.

How the data were processed

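RNA of sorted odontoblasts and of sorted osteoblasts was compared on 4 Agilent two-colour mouse arrays, with 1 RNA of each kind per array. Per the labels, 250 ng of each cDNA was labelled with Cy5 (odontoblast) or Cy3 (osteoblast), and the labels name Cy5 as channel 1. The labels state the 4 arrays as replicates 1 to 4 of 1 comparison, and the series design describes the cells as donor matched. All 4 arrays form a single group, and each array pairs the 2 RNAs, so the ratio within an array is the paired difference. The arrays shared 1 slide and 1 scan, so no batch could be tested. No array had its dyes swapped.

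Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold, for each of 62976 spots, the mean spot intensity and the median local background intensity of both channels, without normalization. The deposited files also hold processed intensity values, after the software's background subtraction and dye normalization, and their log10 ratio of Cy5 over Cy3. A deposited value table of the series holds log10 values whose scale and direction were found by setting them against the scanner files. On each array about 99.3% of its probes lay within 0.0001 (log2) of the software's log10 ratio, and r was 1.00. Its columns had a median of 0, with many values of exactly 0, and no further centring was found. The software's flags, numbers of 0 or 1 in the deposited files, mark outlier, saturated and bright spots. What the authors did after scanning is not given in the sources used here.

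From the scanner intensities, background was corrected with normexp at an offset of 50, and each array was normalized with loess in limma 3.58.1 under R 4.3.3. The 3671 control spots had weight 0 in loess and were then removed. Spot values flagged as outliers (949) were set to missing on that array, 0 spots were saturated, and spots of 1 probe were averaged. Of 55681 probes, 44233 were kept because they lay well above background in the same channel on at least 3 of 4 arrays. Gene symbols came from a RefSeq table of assembly GRCm38.p6, used for names alone. By accession 27235 probes matched, 3581 had a current symbol in the file, 1645 kept the older name in the file (Il1f6 among them) and 23220 had no symbol. Coordinates are those of the probes in the files, on mm9. A gene with several probes is represented by the brightest, and unnamed probes stayed in the fit as features of their own, which gave 37372 features, 19398 of them genes. A mean ratio was fitted with lmFit and tested against 0 with eBayes, two-sided, with Benjamini-Hochberg adjustment over all features, and genes with an adjusted p under 0.05 were called. Where a probe was not well above background in a channel on any array, its fold is a lower bound. It sets the bright channel's mean against the mean, per array, of the higher of the dim probe's value and the lowest value among probes well above background, after loess and Aquantile normalization.

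Lists of genes were fixed before the data were examined, 24 of pathways and tissues and 14 of cell type markers. They were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over all 38 lists, and again with a correlation estimated per list and with fry. All 13 camera calls were lost with an estimated correlation, where many lists shared an adjusted p of 0.536. The estimate itself does not account for every loss. For the transcription factors of jaw and tooth mesenchyme it was -0.00177, below the preset 0.01. Yet camera's unadjusted p for that list rose from 0.000204 to 0.0277. Markers of dental epithelium had an estimate of -0.103, and their unadjusted p rose from 0.00179 to 0.0471. The losses therefore cannot be put down to correlation between genes alone, and they do not refute the list results. Named genes follow a rule fixed at the same time. It takes the 10 genes with the largest ratio in each direction that were called, had 1 sign and were well above background in both channels on all arrays, passing over genes with only a clone or accession name. It adds up to 5 per direction with the largest lower bound, up to 4 called members per list and up to 2 bright uncalled members, and 14 anchor genes. A gene that the rule picked is not reported here, and bright uncalled members are named only for lists with a camera call. Barx1, Nfia, Nfix, Nfic, Pecam1, Cd68, Tyrobp, Fcer1g, H2-Ab1, Kdm5d, Uty and Eif2s3y were named after their values were seen.

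The fit was tested on simulated data for this comparison, with 37372 features and 50 changed features at each of 4 sizes. Each feature was drawn at the spread that eBayes had moderated for it, which varies less between features than the observed spread. The rates that follow may therefore differ from those of the real data. At 2-fold 2% of the changed features were called, at 4-fold 64%, at 8-fold 96% and at 32-fold 98%, with 3 false calls. Of 31 simulated lists of 20 features, the 1 shifted by 1 on the log2 scale was called by camera and 0 of the unshifted ones were. The simulated features were drawn independently of one another. The simulation therefore cannot show how often camera calls unshifted lists of correlated genes. In the real data the estimated correlation was, for example, 0.387 for cartilage markers and 0.251 for the interferon response.

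Alternatives fixed before the data were examined were an offset of 16, no background subtraction, the software's log ratio, the series value table, median centring, scale normalization between arrays, no filter on dim probes, a filter on both channels, the mean of a gene's probes, outlier spots kept, an intensity trend with a robust fit, array weights, an unpaired fit of separate channels, each array left out, and a test against a 1.5-fold change. A fit of arrays 3 and 4 alone was chosen after seeing the data. All alternatives could be run. For the lists, the intensity trend with a robust fit was replaced by camera's variance trend on the mean log2 ratio, without a robust fit.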

Results

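Odontoblasts, the cells that deposit dentin, were compared with osteoblasts, the cells that deposit bone, on 4 two-colour expression arrays. Per the labels and the series design, both cell types came from 2-week-old mice carrying green fluorescent protein under a 2.3 kb piece of the type I collagen promoter. Fluorescent cells were sorted from digested dental pulp and from digested calvarial bone, the bone of the skull vault, of matched donors. Each array held 1 RNA of each kind, labelled with Cy5 for the odontoblast and with Cy3 for the osteoblast. The arrays are called array 1 to array 4 after their replicate numbers. Dyes were not swapped on any array, so the dye and the cell type share 1 ratio. All ratios below are log2 of Cy5 over Cy3, and a positive value means more signal in the channel labelled odontoblast (Cy5). The median spot signal was 10.8 to 15.6 times the local background in Cy3 and 7.09 to 8.17 times in Cy5, and 67.8% to 85.2% of probes per channel lay well above background. The labels do not say how many animals stand behind each array, so p-values measure the spread between these 4 arrays, and their number limits the precision.

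The question of the comparison, per the series title, is how the expression profiles of the 2 cell types differ. Marker genes of the 2 cell types ran against the dye labels. Dspp, which encodes the main non-collagenous protein of dentin, had a mean log2 ratio of -1.95 ± 0.32 (SE, n = 4), so its signal was 3.85-fold higher in the channel labelled osteoblast (Cy3). The direction held on all 4 arrays, but the adjusted p of 0.0602 missed the threshold of 0.05. Nes, which encodes the intermediate filament nestin found in odontoblasts, had ratios between -3.07 and -1.05 on the 4 arrays (SE of the mean 0.35, adjusted p = 0.0689). The ratio of Dmp1, a mineralised matrix protein of dentin and osteocytes, was -1.71 (adjusted p = 0.111). On the bone side, Ifitm5, a membrane protein of mineralising osteoblasts, was 33.2-fold higher in the channel labelled odontoblast (log2 ratio 5.05 ± 0.45 SE, adjusted p = 0.0167). Col1a2, a chain of type I collagen, was 6.91-fold higher there (adjusted p = 0.0230). Because these markers oppose the labels, the text below names channels by dye and label and never by cell type. If the labels were exchanged, every ratio would change sign and each pair of counts would trade places.

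The remaining anchor genes did not pass the test. Log2 ratios were 1.80 for Col1a1 (adjusted p = 0.0520), 3.06 for Spp1 (osteopontin, adjusted p = 0.105), 2.65 for Ibsp (bone sialoprotein, adjusted p = 0.157) and 1.20 for Runx2 (a transcription factor of both lineages, adjusted p = 0.158). Bglap (osteocalcin) had a ratio of 1.34 ± 0.75 (SE), with values of 3.48, -0.32, -0.35 and 2.55 on arrays 1 to 4, and its close copies Bglap2 and Bglap3 can share its signal. Alpl (0.05), Sp7 (0.02), Mepe (0.42) and Phex (0.38) had mean ratios within about 1 SE of 0. Sost, an osteocyte gene, was left out by the filter on dim probes.

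**Figure D1:**
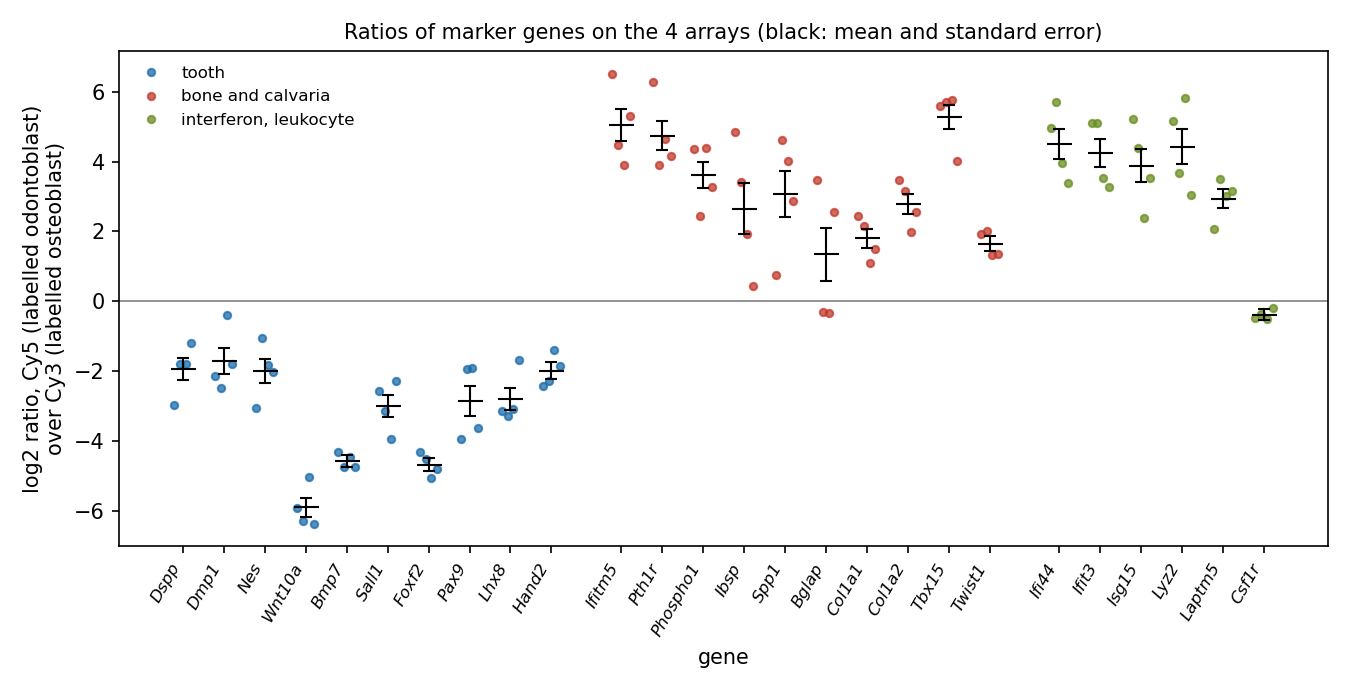
Log2 ratio of Cy5 over Cy3 (vertical axis) for 26 genes (horizontal axis), with 1 coloured point per array, in the order of arrays 1 to 4, and the mean ± SE in black. The genes were picked for the figure after their values were seen, and tooth list members that lie elsewhere, such as Smpd3 and Barx1, are not drawn. Dspp, at -1.95, and the other 9 tooth genes drawn lie below 0 on all 4 arrays, Ifitm5, at 5.05, lies above 0 on all 4, and Bglap spreads over both sides.

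Across the genome, limma called 421 of 19398 genes at an adjusted p under 0.05. Of these, 251 were higher in the Cy5 channel and 170 in the Cy3 channel. Every called gene changed at least 2-fold, so the counts at 2-fold were also 251 and 170, and the median size was 5.60-fold. All 421 had 1 sign on every array that measured them. The split depended on the normalization: with median centring in place of loess, which left the median gene at 0.20 in place of 0.01, the counts were 1155 and 239, or 82.9% in Cy5 against 59.6%. The number of calls depended on single arrays. Without array 1 or without array 2, limma called 0 genes, with 3138 and 3357 genes at an unadjusted p under 0.05 against 4117 on all 4 arrays. Without array 3 it called 178 genes and without array 4 it called 30.

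Comp, a cartilage and tendon matrix protein (probe on chromosome 8, 72905692 to 72905825, mm9), had the largest ratio toward Cy5. It was 121-fold higher there, at a log2 ratio of 6.92 ± 0.50 (SE, n = 4, adjusted p = 0.0107). Mgp, which encodes the calcification inhibitor matrix Gla protein, followed at 6.30 ± 0.71 (adjusted p = 0.0277). Tnmd, the tendon gene tenomodulin on chromosome X, stood at 5.55 ± 0.31 (adjusted p = 0.00648). The next genes were Nfib (5.42), Igsf10 (5.30), Tbx15 (5.27), Ifitm5 (5.05), Abi3bp (32.1-fold), Aspn (4.89) and the imprinted non-coding RNA H19 (4.80). Probes differed in size, from 0.11 to 5.42 over 5 probes of Nfib, from 0.24 to 4.80 over 7 probes of H19 and from 3.32 to 5.30 over 3 probes of Igsf10. Another 5 genes were not well above background in Cy3 on any array and have only a lower bound, which is open to dye bias. Gdf10, a growth factor of the BMP family, was at least 6.99-fold higher in Cy5 (adjusted p = 0.0111) and the antigen-presenting gene H2-Aa at least 6.83-fold (adjusted p = 0.0192). Adgrd1 was at least 5.38-fold higher, Tril at least 4.82-fold and Hgf at least 3.21-fold.

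Nts, the gene of the neuropeptide neurotensin (chromosome 10, 101944967 to 101945026, mm9), had the largest ratio toward Cy3. It was 74.7-fold higher in the channel labelled osteoblast, at a log2 ratio of -6.22 ± 0.18 (SE, n = 4, adjusted p = 0.00544). Wnt10a, a Wnt ligand that tooth development requires (chromosome 1, 74850633 to 74850692, mm9), had the next largest ratio there, -5.91 ± 0.28 (adjusted p = 0.00578). Car2, which encodes carbonic anhydrase 2, stood at -5.57 ± 0.24 (adjusted p = 0.00544). Further genes were Ptprb (-5.09), Serpinb2 (-4.94), the thyroid hormone activating enzyme Dio2 (-4.88), Foxf2 (-4.68), Bmp7 (-4.57) and Pmch (-4.49), the precursor of melanin-concentrating hormone. A bound alone could be given for 3 genes not well above background in Cy5. Il1f6, a cytokine of the interleukin-1 family, was at least 15.0-fold higher in Cy3 (adjusted p = 0.0222), Lipk at least 8.69-fold and Adcy1 at least 4.44-fold.

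Tooth gene lists lay toward the Cy3 channel. Of 12 measured odontoblast and dentin genes, 3 were higher in Cy3 and 0 in Cy5 (6 and 0 adjusted over the list alone). The called members were Wnt10a, Bmp7 and the transcription factor Sall1 (-2.99, adjusted p = 0.0232). The brightest uncalled members lay toward Cy5 on 3 of 4 arrays, Smpd3 (a sphingomyelinase) at 1.41 (adjusted p = 0.218) and Cpne7 at 0.29 (adjusted p = 0.520). The list's median was -0.76 and camera, which compares a list with all other genes, gave an adjusted p of 0.0322 (adjusted p = 0.536 with an estimated correlation). That call was lost with scale normalization between arrays (adjusted p = 0.0636), with camera's variance trend (adjusted p = 0.472) and without array 2 (adjusted p = 0.102). The variance trend followed the mean log2 ratio and not the intensity, without a robust fit. Of 18 transcription factors of jaw and tooth mesenchyme, 4 were higher in Cy3 and 0 in Cy5 (10 and 1 adjusted over the list alone). These were Foxf2, Pax9 (-2.86, adjusted p = 0.0496), Lhx8 (-2.80, adjusted p = 0.0278) and Hand2 (-1.99, adjusted p = 0.0286). Lhx8 and Hand2 were well above background in Cy5 on only 2 arrays. Bright uncalled members were Lhx6 (0.01, adjusted p = 0.991) and Runx3 (0.37, adjusted p = 0.643). The median was -1.06 and the camera adjusted p 0.000967 (adjusted p = 0.536 with an estimated correlation). Barx1, a molar tooth regulator named here after its value was seen, had a ratio of 1.97 with the opposite sign on all 4 arrays (adjusted p = 0.0892), on 2 of which it was well above background in Cy3. Markers of dental epithelium, the enamel-forming tissue that the sort was not aimed at, also lay toward Cy3. Odam (32.0-fold, adjusted p = 0.00615) and Ambn (-3.05, adjusted p = 0.0232), both enamel matrix related, were higher there, out of 10 measured markers (3 adjusted over the list alone), and a second probe of Odam stood at -3.39. Of the bright uncalled markers, Perp had a ratio of -1.65 (adjusted p = 0.219) and Krt14 of -0.10 (adjusted p = 0.769). The median was -0.54 and the camera adjusted p 0.00618 (adjusted p = 0.536 with an estimated correlation), a call lost when both channels had to lie well above background on all arrays (adjusted p = 0.0913).

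Bone lists lay toward the Cy5 channel. Of 20 osteoblast and bone matrix genes, 6 were higher in Cy5 and 0 in Cy3 (12 and 2 adjusted over the list alone). Besides Ifitm5 and Col1a2, they included the parathyroid hormone receptor Pth1r (4.74, adjusted p = 0.0167), the collagen gene Col13a1 (4.08, adjusted p = 0.0192) and the mineralisation phosphatase Phospho1 (3.62, adjusted p = 0.0232). The median was 1.57 and the camera adjusted p 1.37e-06 (adjusted p = 0.536 with an estimated correlation). Transcription factors of calvarial and frontonasal tissue went both ways. Tbx15 and Twist1 (1.65, adjusted p = 0.0334) were higher in Cy5, while Alx1 (-2.86, adjusted p = 0.0319) was higher in Cy3, out of 19 measured (10 and 4 adjusted over the list alone). Prrx1 (0.58, adjusted p = 0.212) and Tcf12 (-0.05, adjusted p = 0.916) were bright and not called. The list's median was 0.76, and its camera adjusted p of 0.0487 (adjusted p = 0.675 with an estimated correlation) rose above 0.05 in most other settings, for example to 0.249 with median centring, to 0.102 without array 2 and to 0.342 without array 3. Of 11 factors that regulate osteoclasts, 1 was called, the Wnt ligand Wnt16 (3.94, adjusted p = 0.0121), with 6 adjusted over the list alone. Bright uncalled members went both ways, Csf1 at 1.09 (adjusted p = 0.385) and Ptgs2 at -1.10 (adjusted p = 0.555). The median was 2.02 and the camera adjusted p 0.00293 (adjusted p = 0.536 with an estimated correlation). Osteocyte genes had no list call, with 1 of 11 called, Ptprz1 (3.22, adjusted p = 0.0484), whose 3 probes ranged from 0.40 to 3.22.

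The matrix gene lists with a camera call lay toward Cy5, as the bone matrix list did, which shares Col1a2 and Col13a1 with the collagen list. Matrix proteases and inhibitors had no list call (median 0.10, camera adjusted p = 0.508). Of 41 collagen genes, 7 were higher in Cy5 and 0 in Cy3 (17 and 5 adjusted over the list alone), among them Col2a1 (4.34, adjusted p = 0.0481), Col13a1, Col8a2 (3.52, adjusted p = 0.00648) and Col1a2. Col2a1 was well above background in Cy3 on 1 array only, and the bright member Col5a1 (0.98, adjusted p = 0.129) was not called. The median was 0.95 and the camera adjusted p 6.65e-06 (adjusted p = 0.536 with an estimated correlation). Of 14 small leucine-rich proteoglycans, matrix proteins that bind collagen fibrils, Aspn, Lum (2.38, adjusted p = 0.0383) and Podn (1.94, adjusted p = 0.0375) were higher in Cy5 and 0 in Cy3 (9 and 2 adjusted over the list alone). Dcn (2.64, adjusted p = 0.0765) and Bgn (0.75, adjusted p = 0.160) were bright and not called. The list had a median of 1.61 and a camera adjusted p of 8.7e-05 (adjusted p = 0.536 with an estimated correlation). Secretory and collagen-processing genes had a median of 0.44 and a camera adjusted p of 0.00180 (adjusted p = 0.605 with an estimated correlation), although only Pcolce2 (3.66, adjusted p = 0.0164) of 27 members was called (4 adjusted over the list alone), and it was well above background in Cy3 on 1 array only. Lox had a ratio of 0.58 (adjusted p = 0.432) and Loxl2 of 0.44 (adjusted p = 0.547). Markers of other connective tissue moved with the called matrix lists, with which they share members. Col2a1 and Col11a2 also count as collagens, and Aspn as a proteoglycan. Cartilage markers had a median of 1.62 with 3 of 13 higher in Cy5 (6 adjusted over the list alone), namely Comp, Col2a1 and Col11a2 (2.22, adjusted p = 0.0403). Fibroblast and periosteum markers had a median of 1.42 with 5 of 16 higher in Cy5 (9 in Cy5 and 2 in Cy3 adjusted over the list alone), including Tnmd, Aspn, Thy1 (4.58, adjusted p = 0.0121) and Dpt (4.46, adjusted p = 0.00544). Not called were the bright cartilage markers Acan (2.30, adjusted p = 0.152) and Col9a2 (0.95, adjusted p = 0.284) and the fibroblast marker Col3a1 (1.23, adjusted p = 0.348). Camera adjusted p-values were 8.04e-06 for the cartilage list and 6.65e-06 for the fibroblast list (for each, adjusted p = 0.536 with an estimated correlation).

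Interferon response genes formed the list with the largest median, 2.33. Of 19 measured members, 11 were higher in Cy5 and 0 in Cy3 (17 and 0 adjusted over the list alone). Ifi44 (4.50, adjusted p = 0.0181), Ifit3 (4.26, adjusted p = 0.0186), Isg15 (3.89, adjusted p = 0.0325) and Ifit1 (3.88, adjusted p = 0.00916) had the largest ratios. Bst2 (1.80, adjusted p = 0.148) and Ddx58 (0.69, adjusted p = 0.215) were bright and not called. The camera adjusted p was 3.47e-15 (adjusted p = 0.536 with an estimated correlation). Macrophage and leukocyte markers lay toward the same channel. Their median was 1.76, and Lyz2 (4.42, adjusted p = 0.0277), Laptm5 (2.93, adjusted p = 0.0186) and H2-Aa were called out of 19 (12 and 0 adjusted over the list alone). The camera adjusted p was 0.000158 (adjusted p = 0.536 with an estimated correlation). The markers that were not called went both ways, with mean ratios of 3.70 for Tyrobp (adjusted p = 0.132) and 3.49 for Fcer1g (adjusted p = 0.145), but -1.45 for H2-Ab1 (adjusted p = 0.343). Csf1r (-0.39, adjusted p = 0.285) and Itgam (0.17, adjusted p = 0.684) lay closer to 0, although other probes reached -2.84 for Csf1r and 1.42 for Itgam.

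A further test of the lists, fry, asks whether a list's genes move on balance one way. Of the 13 lists with a camera call, 5 passed fry, with adjusted p-values of 0.000747 for dental epithelium, 0.00609 for odontoblast and dentin genes, 0.0169 for the interferon response, and 0.0181 for jaw and tooth factors and for fibroblast markers. The other 8 did not, with adjusted p-values of 0.0537 for the proteoglycans, 0.0570 for bone matrix genes, 0.0722 for collagens, cartilage and leukocyte markers, 0.0973 for osteoclast-regulating factors, 0.141 for secretory genes and 0.241 for calvarial factors.

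**Figure D2:**
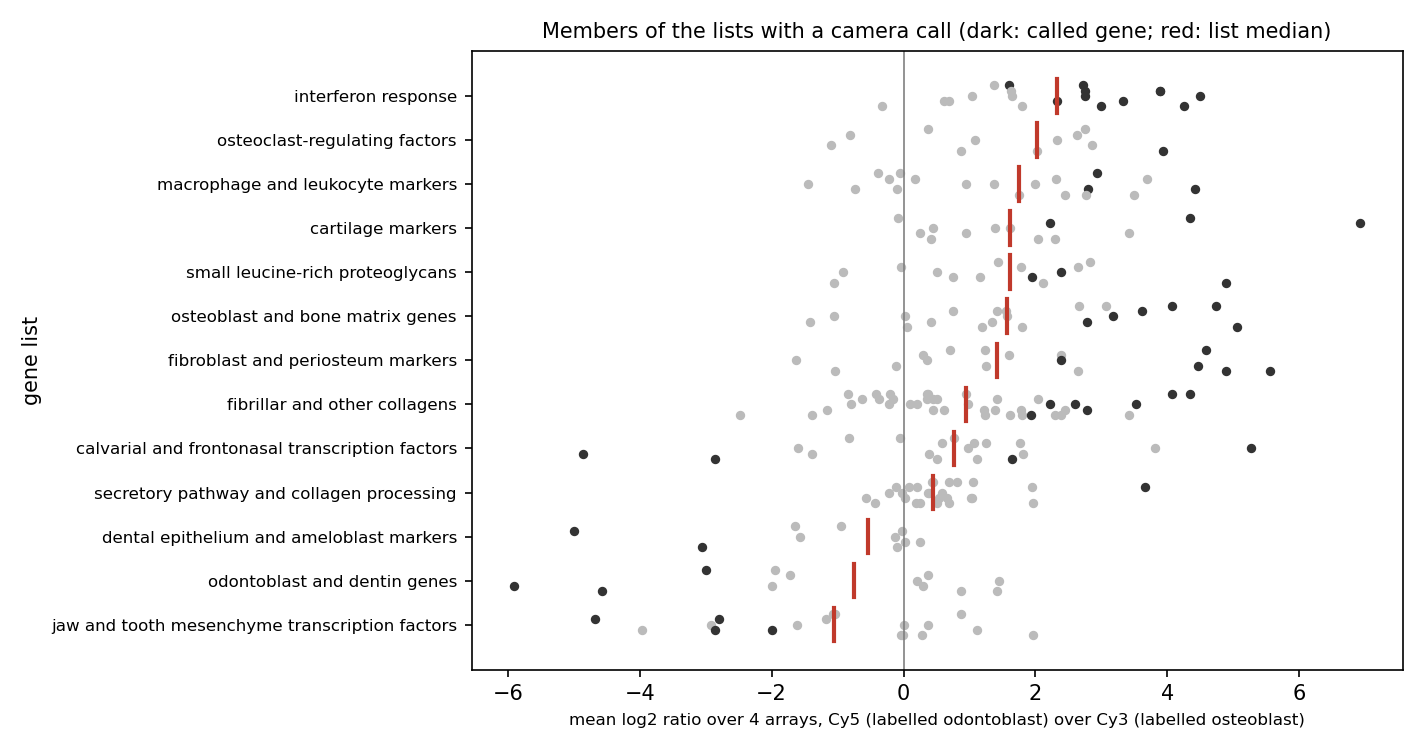
Mean log2 ratio of Cy5 over Cy3 over 4 arrays (horizontal axis) for each member of the 13 gene lists with a camera call at the preset correlation (vertical axis). Dark points passed the test over all genes, grey points did not, and the red line is the list's median, from -1.06 for the jaw and tooth factors to 2.33 for the interferon response.

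Signalling lists held called genes on both sides without a list call. Among 33 measured Wnt pathway genes, Wnt16 was higher in Cy5 and Wnt10a, Lgr6 (-3.51, adjusted p = 0.0312, with a second probe at -2.02) and Wnt5a (-1.09, adjusted p = 0.0488) in Cy3 (7 and 7 adjusted over the list alone). The Wnt antagonist Wif1 (-3.03, adjusted p = 0.0323) was higher in Cy3, the only call among 14 antagonists (1 in each direction adjusted over the list alone). Of 34 BMP and TGF-beta genes, 4 were higher in Cy5 and 2 in Cy3 (7 and 4 adjusted over the list alone). The BMP modulators Chrdl1 (4.14, adjusted p = 0.00974, with a second probe at 1.58) and Bmper (3.85, adjusted p = 0.0101) lay opposite to Bmp7. Of 19 FGF pathway genes, Fgfr2 (3.17, adjusted p = 0.0222) and Spry1 (1.78, adjusted p = 0.0474) were higher in Cy5 and Etv4 (-1.89, adjusted p = 0.0256) and Spry4 (-1.67, adjusted p = 0.0334) in Cy3 (3 and 2 adjusted over the list alone). Of 20 genes of mineral ion handling, Mgp, Phospho1 and the vitamin D receptor Vdr (3.23, adjusted p = 0.0182) were higher in Cy5 and Car2 in Cy3 (3 and 2 adjusted over the list alone). Another 5 lists of signalling and cell state had 1 call each. These were Cdon of the hedgehog list (2.95, adjusted p = 0.0285, with a second probe at 1.36, 2 and 1 adjusted over the list alone), Dll1 of the Notch list (-2.31, adjusted p = 0.0468, with a second probe at -0.06), the ion channel Trpm7 (-1.92, adjusted p = 0.0383), the heat shock gene Hspb1 of the stress list (-2.99, adjusted p = 0.0239, 1 and 6 adjusted over the list alone) and Ndrg1 of the hypoxia list (-1.13, adjusted p = 0.0464). Among cell cycle genes, 0 of 29 were called.

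Markers of other cell types that the sort could hold gave few calls. None of the measured markers of osteoclasts, neutrophils, lymphocytes, red blood cells and megakaryocytes, endothelium, Schwann cells and neurons, or brain was called by limma over all genes. Adjusted over the list alone, 1 osteoclast, 2 Schwann cell and 1 brain marker passed. The smooth muscle gene Cnn1 (-2.60, adjusted p = 0.0334) was the only call in the pericyte list. Myl1 (3.19, adjusted p = 0.00918) was the only call in the skeletal muscle list, with a second probe at 0.76 and a signal well above background in Cy3 on 1 array only. Single calls were Lpl in the adipocyte list (2.54, adjusted p = 0.0211), Adamts18 among 38 matrix proteases and inhibitors (3.69, adjusted p = 0.00729, with a second probe at 1.11 and 2 arrays well above background in Cy3) and B2m in the housekeeping list (2.33, adjusted p = 0.0459). The endothelial marker Pecam1 had a ratio of -4.33 on array 3 and ratios between -0.80 and 0.66 on the other arrays. No sex-linked gene was called, and Xist, the X inactivation RNA, had ratios of -4.34, 2.11, 0.06 and 0.70 on arrays 1 to 4. The medians of the 25 lists without a camera call lay between -0.45 and 0.38.

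The 4 arrays resembled one another only in part. Pearson's r of the log2 ratios across 19395 genes, which are not independent replicates, ran from 0.324 to 0.535 between pairs of arrays, and the 2 lowest values, 0.324 and 0.340, were from pairs with array 3. Of these genes, 6093 (31.4%) had the same sign on all 4 arrays, against 12.5% if signs fell at random and independently. Without a dye swap, a dye bias that repeats on every array could also raise this share. Among 126 called genes with several kept probes, the probes of 7 (5.56%) differed in sign.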

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

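An array was taken to stand apart where its gap to the nearest other array was a large part of the whole range of the 4 arrays (Dixon's test at the 95% level). Of 123 genes, 38 list medians and 12 channel measures, 8 values stood apart, 6 of genes and 2 of lists. Chance alone gives about 1 in 20, so this number is no more than chance would give. The values below are listed for a closer look and are not findings of their own. Array 4 lay closer to 0 than the others for Tbx15, at a log2 ratio of 4.01 against 5.60 to 5.76, and for Lhx8, at -1.68 against -3.28 to -3.10. Array 3 stood apart for Spry4 (-2.22 against -1.52 to -1.46), for B2m (1.14 against 2.61 to 2.87) and for Nfix (4.34 against 1.33 to 1.68). Array 1 stood apart for Dll1 (-3.50 against -2.03 to -1.79). On array 2 the collagen list had a median of 1.87 against 0.56 to 0.75, and the list of matrix proteases and inhibitors 0.52 against -0.01 to 0.02. No channel measure stood apart.

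Features without a gene symbol, which no gene count includes, also differed between the channels. Of 17974 such features, 199 passed the test, 125 higher in Cy5 and 74 higher in Cy3.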

How the results depend on the processing

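No called gene named in the text and no called list changed sign in any alternative run, which the fits on fewer arrays could not have shown for genes with 1 sign on all arrays. The counts moved. The numbers of genes higher in Cy5 and in Cy3, 251 and 170, were 160 and 103 with the software's log ratio, 161 and 103 with the series value table, 443 and 327 with array weights, 483 and 305 with separate channels, unpaired, and 98 and 62 against a 1.5-fold change, a stricter test by construction. With median centring they were 1155 and 239. Counts at 2-fold were 160 and 103, 161 and 103, 426 and 308, 433 and 278, 98 and 62, and in Cy5 1052, in the same order. Without 1 array, which leaves fewer samples, counts at any size and at 2-fold ran from 0 to 103 in Cy5 and from 0 to 75 in Cy3. With arrays 3 and 4 only, chosen after seeing the data, limma called 0 in both directions, with 2099 genes at an unadjusted p under 0.05. The cause of the other shifts was not tested. In the remaining alternatives every count stayed within 1.5 times the main one. The median r between arrays (0.404) was recomputed only with median centring, no filter on dim probes and the software's log ratio. It lay between 0.373 and 0.432.

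Of 76 called genes named in the text, 17 lost their call with the software's log ratio, 14 with no filter on dim probes, 9 with scale normalization between arrays and 26 against 1.5-fold. Without array 1 or 2 all 76 lost it, without array 3 32 and without array 4 62. Dspp passed with scale normalization, with the filter on both channels and with the unpaired fit, at log2 ratios between -2.19 and -1.50 over all settings. Of 13 list calls, at most 2 were lost in any setting but the estimated correlation, with which all 13 were lost. In 4 settings 1 uncalled list gained a call: median centring, array weights, array 2 left out, and arrays 3 and 4 only. With the sign of the arrays' ratios chosen in all 8 ways, the real choice gave 421 called genes and the highest other 0, and 1 choice of 8 cannot give a share under 0.05. Probes not well above background, of 255 genes in Cy3 and 35 in Cy5, limit those genes' folds to bounds.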

Other observations

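The tests in this part were chosen after the results were seen, except the test of the other Xist probe. Genes of the nuclear factor I family of transcription factors were picked because Nfib was among the largest ratios. Nfib (5.42, with probes from 0.11) and Nfia (3.63, with probes from 1.99, adjusted p = 0.0268) were higher in Cy5. Nfix had a ratio of 2.22 (adjusted p = 0.137) and Nfic, which tooth root formation requires, a ratio of -0.43 (adjusted p = 0.419). Differences between the family's members were not tested.

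Tooth genes lay toward the channel labelled osteoblast and bone genes toward the channel labelled odontoblast. A mix-up of single arrays is argued against, since the median of the tooth lists lay below that of the bone matrix list on 4 of 4 arrays. An exchange of the dye labels in the record for all arrays stays open, and the share of 7 called tooth list members that were higher in Cy3, 100%, only restates the pattern and lends it no support. Dye bias of single probes may add to the ratios and cannot be told apart without a dye swap, though other kept probes shared the sign in 7 of 8 tooth or bone list members (87.5%, exact 95% interval 47.3% to 99.7%), a test narrowed to list members after a first run over all called genes, where it was 119 of 126. A true difference between the 2 tissues in the labelled direction was not tested, and it would place the tooth lists above the bone matrix list. On the 4 arrays the tooth lists' median lay between -1.24 and -0.39 and the bone matrix list's between 0.88 and 2.34. These values argue against it for the lists as a whole. Uncalled members such as Smpd3 (1.41) and Barx1 (1.97) lay the other way.

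Genes of the sex chromosomes differed between the channels of an array, although the donors are described as matched. On array 1 Xist stood at 6.65 in Cy5 and 10.99 in Cy3 (log2 intensity), while Ddx3y, on the Y chromosome, stood at 10.56 and 10.71. All 4 Y-linked genes were well above background in both channels of array 1. On array 2 Xist was at 13.13 and 11.02 and Ddx3y at 9.04 and 10.63. On array 3 Xist was at 13.31 and 13.26. There Ddx3y, Kdm5d and Uty were not well above background in either channel, and Eif2s3y was in Cy5 alone. A fault of 1 Xist probe is argued against by the other kept probe, with a log2 ratio of -1.98 on array 1. Different shares of male and female RNA in the 2 channels stay a possible explanation that the values do not decide, since all 4 Y-linked genes ran opposite to Xist on array 2 but on array 1 Kdm5d (0.78) and Uty (1.16) did while Ddx3y (-0.15) and Eif2s3y (-0.70) did not, which leaves 1 of 2 arrays with a large Xist ratio that meets the test.

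Leukocyte and interferon response genes both lay toward Cy5. Leukocytes that passed the fluorescence sort are a candidate source, and 12 of 19 markers (63.2%) were higher in Cy5 on all 4 arrays. But Cd68 (-0.10), Csf1r (-0.39) and Itgam (0.17) were not. Other probes reached -1.20 for Cd68, -2.84 for Csf1r and 1.42 for Itgam. The probes used were bright in both channels, with mean log2 intensities of 16.19 in Cy5 and 16.02 in Cy3 for Itgam. Those for Csf1r were 13.98 and 14.36, against 14.27 and 9.84 for the called marker Lyz2. Whether the Itgam and Csf1r probes measured these genes alone was not tested, so their flat ratios are weak evidence against leukocytes. H2-Ab1 (-1.45) also lay toward Cy3 in the mean. The values therefore do not decide whether leukocytes were the source. Whether the same cells could carry the interferon genes cannot be told apart from a response of the sorted cells with 4 arrays. The leukocyte median was highest on array 3, against 0.67 to 1.24 on the others, but the interferon median was highest on array 1 (2.73 against 2.29 on array 3), and on array 3 it lay 0.0699 above its median over the other 3 arrays, with an SD of 0.27 between arrays. A difference between the 2 tissues stays open and was not tested.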
